A study of Mus musculus with 8 samples.

How the data were processed

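Brown adipose tissue of 8 male C57BL/6J mice was measured on 1-colour Affymetrix Mouse Gene 2.0 ST arrays, 1 mouse per array, with 200 ng of total RNA from each. The labels put 3 arrays in the wild-type (WT) group and 5 in the group with a deleted Abhd15 gene (Abhd15 KO). They give an age of 14 weeks in one place and up to 14 weeks on chow in another, and no litter, cage, harvest day or scan date was given in the sources used here.

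The deposited values are on a log2 scale, 1 value per probe set and array, and per the submitters' processing notes they were made with RMA and the oligo package, with no version given. The design text per the labels also names Affymetrix Expression Console, so which program made the deposited table is not settled. RMA corrects background, quantile-normalizes the probes and summarises them per probe set. Such quantile normalization makes the arrays' overall distributions nearly alike, and a change shared by most genes would not be seen. The genome build and the probe positions were not given in the sources used here, so no coordinates are printed. The table held 41345 probe sets with values from 0.49 to 13.3. Array medians lay between 3.00 and 3.04, and correlations between arrays over all probe sets lay between 0.964 and 0.975, so no array was a copy of another. Arrays give no read depth. Their number and their signal over background set the precision.

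Probe sets were named through the platform annotation, with symbols checked by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6 (23328 matched, 0 symbols updated). In that annotation 23521 probe sets had 1 gene symbol, 1814 had several and were not used to name a gene, and 16010 were unnamed. Of several probe sets of a gene, the one with the highest mean over all arrays stood for it, which left 22180 genes. A dim limit of 2.88 log2 was set at the 95th percentile of 1400 probe sets for olfactory and vomeronasal receptors, which brown fat is taken not to use. The 13223 genes above it in at least 3 arrays were tested.

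The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, 1 group term) on the deposited values, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are Abhd15 KO minus WT in log2 units. Their 95% confidence intervals come from the moderated fit and are not adjusted for the number of genes. Single values were also compared by an exact two-sided permutation test over the 56 splits of 8 arrays into 3 and 5, which allows no p below 0.0179. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists with at least 5 tested members. Lists of B cell, neutrophil and mast cell, erythroid and epidermal markers had fewer and were not tested. Estimated correlations, fry and a test on ranks stood beside it. Each list was also tested member by member, adjusted over the list alone. The neighbours of Abhd15 were counted within 5 Mb on each side, using the RefSeq table only for which genes lie near it, and compared with all other tested genes by Fisher's exact test, two-sided.

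The design, the gene lists and most alternatives were fixed before the data were examined. Genes are named by a rule fixed at the same time. It names 9 genes of interest whatever their result. Per direction it takes up to 10 genes past the threshold without overlap between the groups, filled up with those of lowest unadjusted p without overlap, which are given as values only. Predicted gene models, microRNAs and small nucleolar RNAs are not named under that part. For each list it picks the 4 members of lowest p if the list passes and 2 otherwise. The text does not give these members for every list. Genes named outside the rule are marked as such. The alternatives tried were the replicate number as a block, other dim-gene filters, another normalization or centring, a mean-variance trend with robust fitting, array weights, other ways to combine probe sets, the mean of the muscle genes as a covariate, a looser threshold, a minimum fold of 1.2 and leaving out each array in turn. Leaving out pairs of arrays, Angptl8 as a covariate and the estimated correlation within the other settings were added after the data were seen.

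The steps were tested on simulated data for this comparison, with 13223 genes fitted and 50 genes changed per fold size. All fold sizes were changed in the same data, and the Benjamini-Hochberg cutoff loosens as more genes pass. The shares called therefore do not apply where only a few genes change. With values drawn from each gene's mean and moderated residual SD, 20% of 1.5-fold changes, 84% of 2-fold, 94% of 3-fold and 98% of 4-fold changes were called, and 10 of 13023 unchanged genes. With folds added to the real values the shares were 24%, 70%, 86% and 96%, and 6 of 13023 other genes were called. Of 20 simulated lists of 25 genes shifted by 0.3 log2, camera called 20, and of 80 unshifted lists it called 0. The members of those lists were simulated independently of each other.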

Results

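Gene expression was measured in brown adipose tissue, the heat-producing fat depot, of 3 WT and 5 Abhd15 KO male mice that were given chow again for 1 h after an overnight fast. ABHD15 is an adipocyte protein of the alpha/beta hydrolase family that has been reported to bind phosphodiesterase 3B, an enzyme through which insulin restrains lipolysis. The comparison asks which transcripts differ in brown fat of the mutant shortly after feeding.

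Abhd15 itself was not lower in the arrays labelled Abhd15 KO. Its brightest probe set (17253297) read 6.01 ± 0.19 log2 in WT (SD, n = 3) and 6.12 ± 0.27 in the arrays labelled Abhd15 KO (SD, n = 5), a difference of 0.11 with a 95% confidence interval of −0.27 to 0.49 (exact two-sided permutation p = 0.518). The 8 arrays read 5.87, 5.94 and 6.23 in WT replicates 1 to 3 and 6.32, 6.14, 5.68, 6.35 and 6.13 in the arrays labelled Abhd15 KO, replicates 1 to 5. A second Abhd15 probe set (17266259) read 3.52 ± 0.74 in WT and 3.81 ± 0.28 in the arrays labelled Abhd15 KO (exact permutation p = 0.518). One shared with the adjoining gene Trp53i13 (17266245) read 4.57 ± 0.14 and 4.42 ± 0.17 (exact permutation p = 0.268). A probe set outside the deleted part of a gene checks nothing, and the deleted part is not given in the sources used here, so every direction below rests on the labels alone. Y-linked Eif2s3y read between 7.81 and 8.27 and Xist, which is expressed from an inactive X chromosome, between 1.30 and 2.17 in the 8 arrays, as male samples would.

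No gene of fat storage, lipolysis or heat production passed the test. Ucp1, the uncoupling protein of brown fat, read 12.66 ± 0.13 in WT and 12.73 ± 0.15 in the arrays labelled Abhd15 KO (difference 0.07, 95% confidence interval −0.20 to 0.35). Pde3b, the gene of phosphodiesterase 3B, read 10.85 ± 0.06 and 10.89 ± 0.12 (0.03, −0.21 to 0.28). The lipases Pnpla2 and Lipe differed by 0.07 (−0.16 to 0.30) and 0.01 (−0.21 to 0.23), and the fatty acid synthase gene Fasn by 0.02 (−0.24 to 0.27). Perilipin 1 (Plin1) differed by −0.20 (−0.68 to 0.28), and Irs2, an adaptor of the insulin receptor that fasting induces in several tissues, by −0.46 (−1.16 to 0.25). With limma, 0 of 13223 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.9997. At an unadjusted p under 0.05 there were 528 genes, 295 higher and 233 lower in the arrays labelled Abhd15 KO, where chance alone gives 661. The groups did not overlap in 366 genes (2.77%), and chance gives 3.57%. The median half-width of the 95% confidence intervals was 0.36 log2, and 0 of 9189 tested probe sets with no symbol or several passed (497 at an unadjusted p under 0.05).

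**Figure D1:**
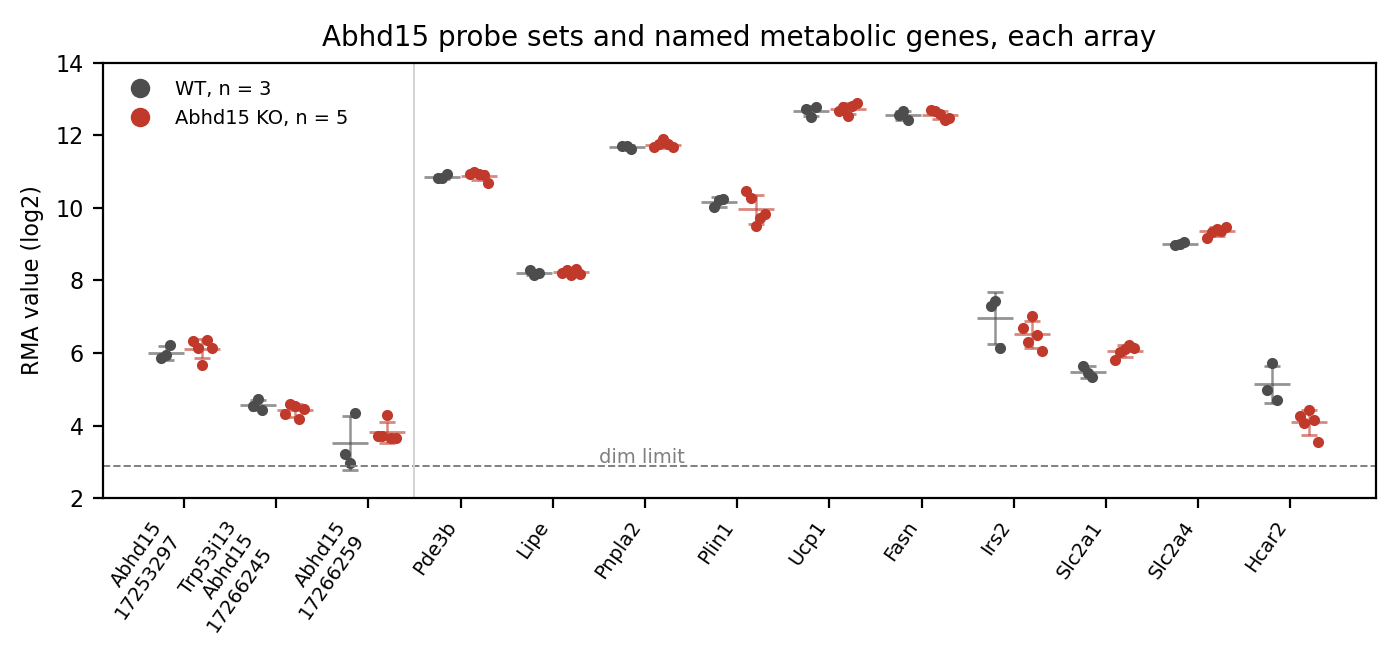
RMA values (log2, vertical axis) of the 3 probe sets that name Abhd15 and of 10 genes of lipid and glucose handling, with 1 point per array (grey, WT, n = 3; red, arrays labelled Abhd15 KO, n = 5) and bars for the mean and SD. The brightest Abhd15 probe set reads between 5.68 and 6.35 in the 8 arrays, with no array near the dim limit of 2.88 drawn as a dashed line.

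The gene Slc2a1 was among those of lowest unadjusted p on the higher side, and Hcar2 and Mvd were among those on the lower side, without passing the adjusted threshold. Slc2a1, the widely expressed transporter GLUT1, read 5.48 ± 0.16 in WT and 6.06 ± 0.16 in the arrays labelled Abhd15 KO, a difference of 0.58 (0.29 to 0.87, exact permutation p = 0.0179). Hcar2, a receptor for the ketone body beta-hydroxybutyrate that restrains lipolysis, read 5.14 ± 0.52 and 4.09 ± 0.34, a difference of −1.05 (−1.62 to −0.47, exact permutation p = 0.0179). Mvd, an enzyme of sterol synthesis, read 4.65 ± 0.16 and 3.97 ± 0.30 (−0.68, −1.08 to −0.27). Only genes whose groups do not overlap were taken here. An exact permutation p at or near its lowest possible value follows from that choice and is no separate support. The other genes of lowest p on the higher side were Rccd1 (0.74), Ybey (0.64), Fhl5 (0.56), Trib2 (0.63), H2aj (0.79), Ccdc85b (0.94), Usp2 (0.54) and Rpl26 (0.75), each given as its log2 difference, and Cnih2. On the lower side they were Rhox6 (−0.66), Ppcs (−0.61), Olfml1 (−0.70), Nenf (−0.44), Sytl4 (−0.51), Hspb9 (−0.48), Sprr1b and Treml1. No difference is given for Cnih2, whose WT mean (2.59) lay below the dim limit of 2.88, or for Sprr1b (2.45) and Treml1 (2.87), whose means in the arrays labelled Abhd15 KO lay below it. Rpl26, H2aj, Rhox6 and Sprr1b belong to families with close copies or processed pseudogenes and are uncertain for that reason, and Rpl26, H2aj, Rhox6, Rccd1, Ccdc85b, Olfml1, Sytl4 and Hspb9 had a group mean less than 1 log2 above the dim limit. In every gene of this paragraph the adjusted p from limma was 0.9997.

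Skeletal muscle and macrophage transcripts were the 2 of 28 lists called by camera, both lower in the arrays labelled Abhd15 KO. All 30 muscle genes were lower, with a median of −0.54 (adjusted p = 0.000901), and 20 of 26 macrophage and inflammation genes were lower, with a median of −0.20 (adjusted p = 0.0044). With limma 0 members of either list passed over all genes and 0 adjusted over the list alone. Neither call held with a correlation estimated for each list (adjusted p = 0.952 for both with an estimated correlation). Tnnt1 and Tnnc2, troponins of slow and fast fibres, differed by −0.87 (−1.83 to 0.09) and −0.91 (−2.30 to 0.48). Ampd1, the AMP deaminase of muscle, differed by −0.78 (−2.13 to 0.56) and the sarcomere gene Tcap by −0.82 (−2.34 to 0.71). The muscle genes spread widely inside both groups: the list mean, relative to its mean over all arrays, was 1.65, 0.50 and −1.14 in WT replicates 1 to 3 and −0.12, −1.68, −0.34, 0.87 and 0.25 in the arrays labelled Abhd15 KO, replicates 1 to 5 (difference −0.54, −2.54 to 1.45, exact permutation p = 0.518). Without WT replicate 1 the median of the muscle list was 0.16, the opposite direction, without WT replicate 3 it was −1.32, and without Abhd15 KO replicate 2 it was −0.12 (adjusted p = 0.491).

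In the macrophage list, the pore-forming protein gene Mpeg1 differed by −0.60 (−1.13 to −0.07), the chemokine Ccl6 by −0.59 (−1.14 to −0.03), the endotoxin co-receptor Cd14 by −0.37 (−0.83 to 0.08) and Clec7a, a receptor for fungal glucans, by −0.37 (−0.84 to 0.11). The mean of this list differed by −0.20 (−0.72 to 0.33, exact permutation p = 0.393). Its call was lost without WT replicate 2 (median 0.01, adjusted p = 0.684), WT replicate 3 (−0.17, 0.10), Abhd15 KO replicate 2 (−0.09, 0.336) and Abhd15 KO replicate 3 (−0.19, 0.0902). Its median was −0.44 without WT replicate 1 and −0.30 without Abhd15 KO replicate 1. The list means were highest in WT replicate 2 (0.37) and Abhd15 KO replicate 1 (0.32), the arrays lowest in Angptl8. Without both the macrophage median was −0.10 and the muscle median −0.48 (adjusted p = 0.0844 for both), and with Angptl8 as a covariate the macrophage median was −0.11 (adjusted p = 0.0549). Without the pair lowest in muscle genes the macrophage median was −0.08 (adjusted p = 0.588). The muscle list moved in the same direction between the groups.

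**Figure D2:**
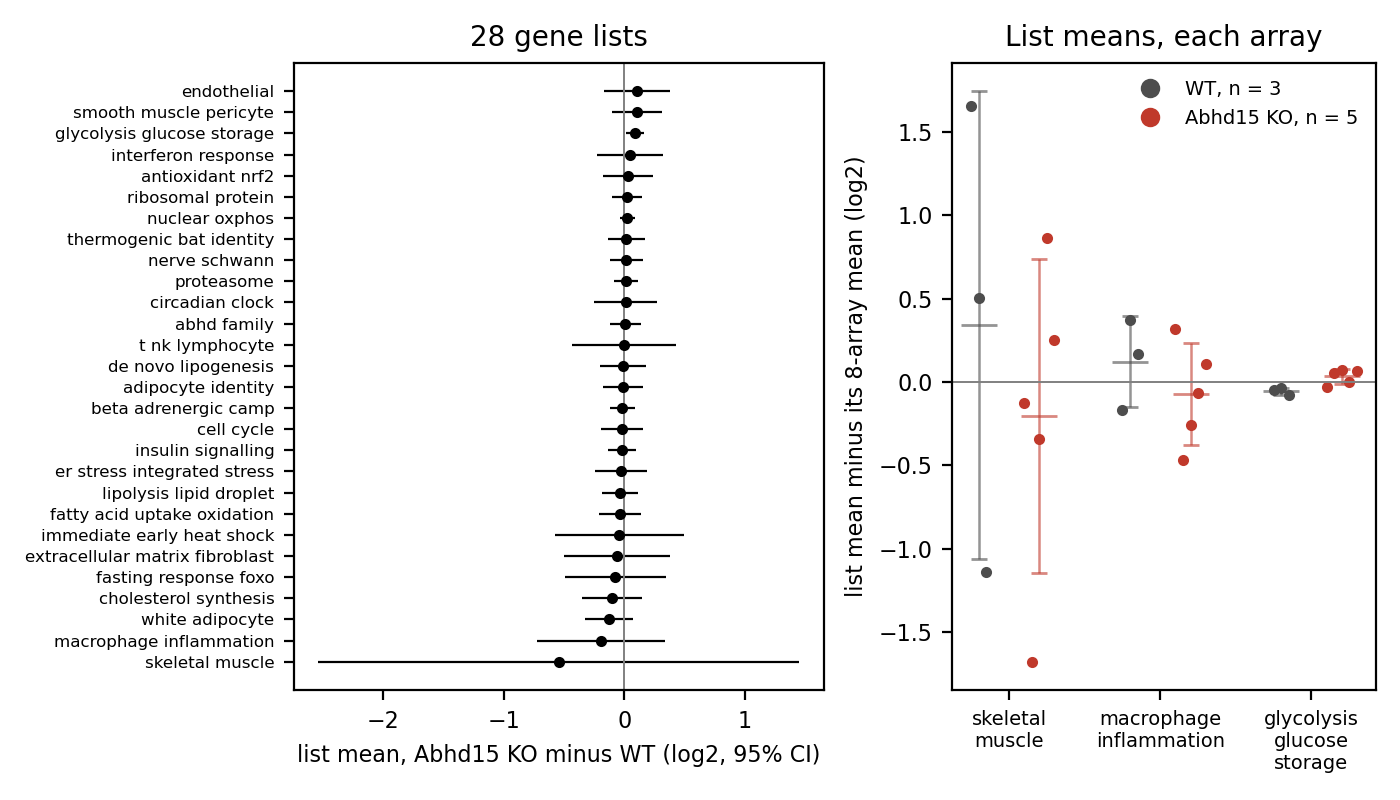
Left, difference of the list means (Abhd15 KO minus WT, log2, horizontal axis) with 95% confidence intervals for 28 gene lists. Right, the mean of 3 lists in each array relative to its mean over 8 arrays (log2, vertical axis), with 1 point per array (grey, WT, n = 3; red, arrays labelled Abhd15 KO, n = 5) and bars for the mean and SD. The muscle list spans −1.68 to 1.65 over the arrays, far more than its group difference of −0.54.

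Glycolysis and glucose storage genes were called under some settings and not in the planned test. Of 26 members 19 were higher in the arrays labelled Abhd15 KO, with a median of 0.07 (camera adjusted p = 0.106, and adjusted p = 0.952 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The list mean differed by 0.09 (0.02 to 0.16, exact permutation p = 0.0357), which after adjustment over the 28 lists was p = 0.963 in the exact permutation test. Slc2a4, the insulin-responsive transporter GLUT4, read 9.01 ± 0.05 in WT and 9.35 ± 0.12 in the arrays labelled Abhd15 KO, a difference of 0.34 (0.10 to 0.58, exact permutation p = 0.0179), and Gys2, a glycogen synthase, differed by 0.33 (0.00 to 0.65). Camera called this list with trend and robust fitting (adjusted p = 0.0163), with array weights (0.0382), without WT replicate 2 (median 0.13, 0.0438) and without Abhd15 KO replicate 1 (median 0.06, 0.0365), but with an estimated correlation in these fits the adjusted p was 0.942 or more. Without WT replicate 1 the median was 0.04 (adjusted p = 0.409) and without WT replicate 3 it was 0.05 (0.405). Over the alternatives that change 1 choice its adjusted p ranged from 0.0122 to 0.958. In the insulin signalling list 13 of 28 members were higher and 15 lower. One member, Slc2a1, passed when adjusted over the list alone and 0 over all genes. It was the only such pass in the 28 lists. Slc2a1 is among the genes of lowest p named above, so this is no separate support. Among 19 endothelial genes 17 were higher, with a median of 0.08 (camera adjusted p = 0.0786), led by the adhesion molecules Pecam1 (0.25, −0.02 to 0.51) and Esam (0.24, −0.10 to 0.57). Without Abhd15 KO replicate 4 the endothelial list was called (median 0.15, adjusted p = 0.000828), as it was with trend and robust fitting (0.0305) and by the test on ranks (0.0255). With an estimated correlation the adjusted p was 0.979 without Abhd15 KO replicate 4, 0.962 with trend and robust fitting and 0.952 with all arrays. The endothelial median was 0.14 without WT replicate 1 (adjusted p = 0.0529), 0.05 without WT replicate 2 (0.684) and 0.02 without the pair lowest in Angptl8 (0.702).

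The lists of brown fat function were not called in the planned test. In the thermogenic list 15 of 24 genes were higher (median 0.07), with Nrg4, a secreted growth factor, at −0.25 (−0.58 to 0.09) and Eva1a below the dim limit in the arrays labelled Abhd15 KO (2.78). In the lipolysis and lipid droplet list 11 of 23 were higher (median −0.00), with Hilpda, an inhibitor of the main triglyceride lipase, at −0.35 (−0.82 to 0.12) and its other inhibitor G0s2 at 0.28 (−0.18 to 0.74). In the nuclear respiratory chain list 30 of 47 were higher (median 0.02), led by the cytochrome c oxidase subunit Cox7c at 0.49 (0.11 to 0.88) and Atp5c1 at 0.19 (−0.05 to 0.44). In the lipogenesis list 10 of 23 were higher (median −0.02), in fatty acid uptake and oxidation 14 of 30 (−0.01), in cholesterol synthesis 7 of 19 (−0.12) and in the fasting response 11 of 24 (−0.10). The cholesterol synthesis median ranged from −0.17 to 0.01 over the 23 alternatives, and none of them called that list. The fasting list was called without WT replicate 3 (median −0.19, adjusted p = 0.0424), but not with an estimated correlation in the same fit (adjusted p = 0.928), and its median was 0.09 without WT replicate 2 (adjusted p = 0.684). In the beta-adrenergic list 16 of 26 were higher (0.02), with the inhibitory G protein Gnai1 at −0.37 (−0.70 to −0.04) and Gnas at 0.20 (−0.03 to 0.43). The Gnas probe set read only 3.96 in WT, not far above the dim limit of 2.88. The adipocyte identity list had 7 of 18 members higher (−0.02), with the hormone gene Retn at −0.30 (−0.57 to −0.04) and Cebpb at 0.37 (−0.05 to 0.79). The other Abhd genes had 9 of 18 higher (0.00), led by Abhd8 (−0.41, −0.83 to 0.02) and Abhd12 (−0.28, −0.58 to 0.02). In each of these lists 0 members passed over all genes and 0 adjusted over the list alone, and the camera adjusted p ranged from 0.186 for cholesterol synthesis to 0.955 for the beta-adrenergic list.

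Markers of other cell types and of handling gave the following medians, with 0 members past the threshold over all genes or adjusted over the list alone in any of them. White adipocyte genes had a median of −0.21 (8 of 14 lower), smooth muscle and pericyte genes 0.16 (8 of 12 higher), fibroblast matrix genes −0.07 (17 of 27 lower), T and NK cell genes 0.02 (4 of 6 higher) and Schwann cell genes −0.01 (4 of 8 higher). Interferon response genes had a median of 0.01 (10 of 19 higher), immediate early and heat shock genes 0.02 (13 of 23), clock genes −0.05 (8 of 17), integrated stress genes −0.03 (10 of 22), cell cycle genes −0.02 (6 of 14), proteasome genes 0.01 (17 of 30) and antioxidant genes 0.05 (13 of 21). Ribosomal protein genes had a median of −0.07 but a mean of 0.02, with Rpl5 at 0.69 (0.20 to 1.19) and Rps18 at −0.34 (−0.62 to −0.06). Rpl5 read 4.38 in WT, and both genes are uncertain for the same reason as Rpl26. Median and mean also differed in sign for the immediate early list (mean −0.04), clock list (0.01), T and NK list (−0.00), Schwann cell list (0.02), beta-adrenergic list (−0.02) and the other Abhd genes (0.01). Without Abhd15 KO replicate 1 the matrix list (median −0.17) and the white adipocyte list (−0.27) were called (adjusted p = 0.0365 for both), but not with an estimated correlation in the same fit (adjusted p = 0.969 for both). Without WT replicate 2 their medians were 0.03 and −0.08 (adjusted p = 0.684 and 0.683). With all arrays the camera adjusted p of the lists in this paragraph ranged from 0.186 for white adipocyte genes to 0.951 for Schwann cell genes.

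Genes beside Abhd15 did not pass the test. Of 124 tested genes within 5 Mb, 0 passed the adjusted threshold, and 5 (Mir212, Slc43a2, Myo18a, Rab34 and Traf4) had an unadjusted p under 0.05 by limma. That was 4.03% against 3.99% of all other tested genes (Fisher's exact test, two-sided, p = 1). These 5 are named because of their number, after their values were seen. Within 2 Mb the share was 6.06% against 3.98% (Fisher's exact test, p = 0.337) and within 10 Mb 5.43% against 3.96% (p = 0.212, Fisher's exact test). The 15 genes counted within 10 Mb include Slc2a4, Rpl26, Ccl6 and Wfdc21. Nnt, which C57BL/6J mice carry in a broken form, read 3.05 to 3.65 in the 8 arrays, close to the dim limit, and differed by −0.28 (−0.61 to 0.06, exact permutation p = 0.125).

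Several genes varied more between mice of the same label than between the labels, and they are named here after their values were seen. Angptl8, a secreted regulator of lipoprotein lipase that feeding induces, read 10.81, 7.95 and 10.45 in WT replicates 1 to 3 and 7.90, 10.81, 10.42, 10.42 and 10.80 in the arrays labelled Abhd15 KO, replicates 1 to 5. The clock-related repressor Bhlhe41, the receptor gene Kit and Mid1ip1, a partner of acetyl-CoA carboxylase, were also lowest in WT replicate 2 and Abhd15 KO replicate 1. Bhlhe41 read 4.69 and 4.85 there against 7.44 to 8.07 in the other 6 arrays, Kit 5.32 and 5.31 against 7.46 to 8.16, and Mid1ip1 4.98 and 4.93 against 6.55 to 7.03. The immediate early genes Fos and Egr1 were highest in the same arrays. Fos read 5.64 and 4.96 against 2.58 to 3.64, and Egr1 6.58 and 5.39 against 3.21 to 4.79. Nr4a2, another gene of the immediate early list, went the other way, with 5.69 and 5.74 against 6.33 to 7.11. Acta1, the actin of skeletal muscle, ranged from 6.71 to 10.49 and the fast myosin gene Myh4 from 7.31 to 10.88. Of the 50 genes with the largest residual SD, 19 were among the 30 of the muscle list. The first principal component held 25.3% of the variance and placed WT replicate 2 (28.1) and Abhd15 KO replicate 1 (21.6) apart from the other 6 arrays (−17.0 to 0.97).

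**Figure D3:**
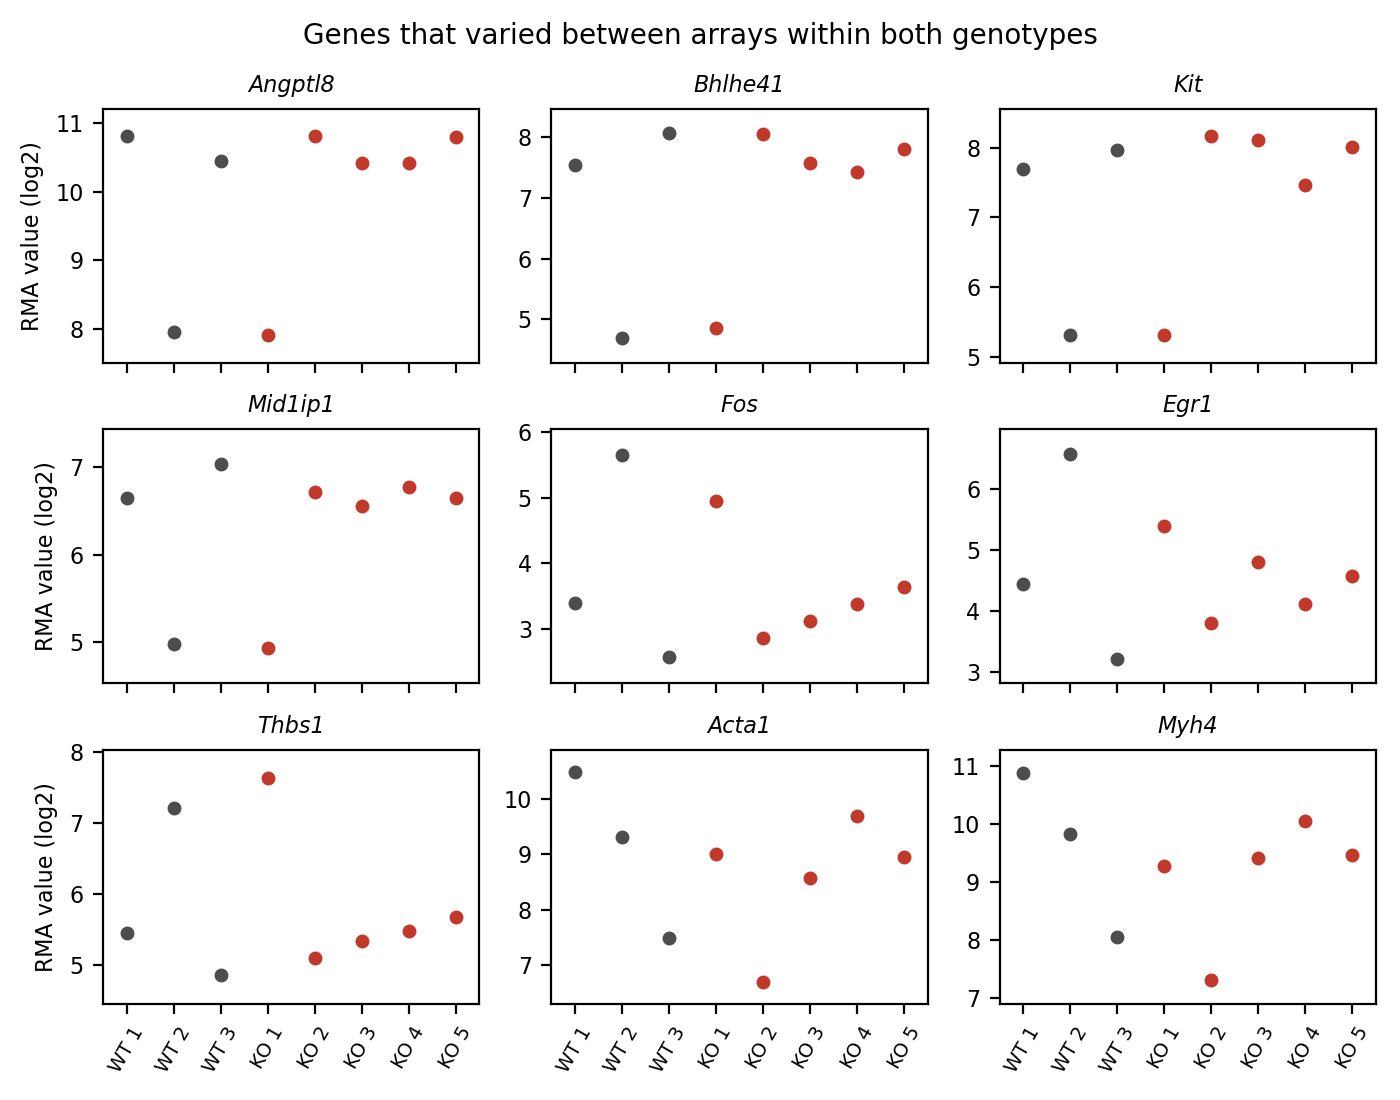
RMA values (log2, vertical axes that differ between panels) of 9 genes in each of the 8 arrays (grey, WT; red, arrays labelled Abhd15 KO), 1 point per array. Angptl8 reads 7.95 in WT replicate 2 and 7.90 in Abhd15 KO replicate 1 and between 10.41 and 10.81 in the other 6 arrays, while Acta1 and Myh4 follow another order.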

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

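The tests of explanations for the Abhd15 level and the comparisons with other splits of the arrays were chosen after the values were seen; the Abhd15 difference itself was planned.

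At an unadjusted p under 0.05 by limma the genotype labels gave 528 genes, 38 of the 56 splits of the 8 arrays into 3 and 5 gave as many or more, and the highest other split gave 1587, so chance is not excluded. For the 0 genes past an adjusted p of 0.05 the splits decide nothing, since all 56 give at least 0 (highest other 1). The split that gave 1587 set WT replicate 2 and Abhd15 KO replicates 1 and 3 against the rest. Abhd15 KO replicate 3 did not share the low Angptl8 of the other arrays in that set (10.42). Every split with WT replicate 2 and Abhd15 KO replicate 1 together in the set of 3 gave 791 to 1587. The split with WT replicate 1 and Abhd15 KO replicates 4 and 5 gave 1383. These counts point to a structure of the samples that is not genotype. For the 2 gene lists called by camera, 43 of the 56 splits gave as many or more, and the highest other split gave 8, so chance is not excluded for these either.

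Abhd15 was not lower in the arrays labelled Abhd15 KO. A probe set that reads only background is argued against by its mean, which lay 3.20 log2 above the dim limit. A probe set outside the deleted part of the gene could leave the difference of 0.11 as it is, and this stays open because neither the probes nor the deletion could be placed here. An exchange of arrays between the groups stays open for the same reason: the largest gap between neighbouring values was 0.20 log2 within a range of 0.67, which bears on an exchange only if the probe set reads the deleted part. That all 8 mice carry the same allele is open too, and no biological explanation was tested.

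Among the 112 results checked in the 5 arrays labelled Abhd15 KO, 9 had a lone array farther from the others than Dixon's critical ratio of 0.71 (its gap to the nearest other array divided by the range), where chance gives 5.6. Pde3b had a low value in replicate 5 (10.68 against 10.89 to 10.97 in the others, ratio 0.72). Nnt (3.64 against 3.05 to 3.20, ratio 0.738), H2aj (4.62 against 4.22 to 4.31, ratio 0.785) and Hspb9 (3.22 against 2.85 to 2.95, ratio 0.728) had a high value in replicate 4. Cd14 was low in replicate 2 (3.82 against 4.41 to 4.51, ratio 0.855), Rps18 high in replicate 3 (5.82 against 5.73 to 5.75, ratio 0.758) and Nr4a2, an immediate early gene, low in replicate 1 (5.74 against 6.75 to 7.11, ratio 0.74). The mean of the thermogenic list was low in replicate 3 (−0.14 against 0.02 to 0.08, ratio 0.744) and that of the nuclear respiratory chain list high in replicate 2 (0.08 against −0.02 to 0.00, ratio 0.827). The 3 WT arrays were too few for this check.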

How the results depend on the processing

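The count of genes past an adjusted p of 0.05 was 0 under all 23 alternatives (adjusted p from 0.672 to 1). In simulation 20% of 1.5-fold and 84% of 2-fold changes were called, and 24% and 70% with folds added to the real values. Those data held many changed genes at once, which loosens the Benjamini-Hochberg cutoff. The shares therefore do not tell how many changes would be found where only a few genes change. At an unadjusted p under 0.05 there were 1019 genes with no filter on dim genes, as 22180 genes were then tested, 67 when a fold of 1.2 was required, and 453 to 654 when 1 array was left out. The counts by unadjusted p were added after the data were seen, as were the settings that leave out 2 arrays, Angptl8 as a covariate and the estimated correlation within the other settings, where 0 lists were called in 20 of 20 (adjusted p 0.901 or more). The same-numbered arrays of the groups did not deviate together (correlations −0.26, −0.10 and 0.02). The highest correlation between a WT and an Abhd15 KO array was 0.39, for WT replicate 2 and Abhd15 KO replicate 1. So few arrays cannot exclude a shared day or litter, and the replicate numbers are taken only as names of arrays. With the replicate number as a block 0 genes passed, 422 had an unadjusted p under 0.05 and 3 lists were called. The endothelial list was among them (median 0.22 against 0.08, camera adjusted p = 0.000628, and adjusted p = 0.986 with an estimated correlation). Abhd15 KO replicates 4 and 5 had no WT array in their block, so that fit compared only replicates 1 to 3 of each group.

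The count of 2 lists became 4 with trend and robust fitting, 0 with the muscle list mean as a covariate, 0 with an estimated correlation, 0 with fry, 1 without the pair of arrays lowest in Angptl8, 1 without the pair lowest in muscle genes and 1 with Angptl8 as a covariate. It ranged from 0 to 5 when 1 array was left out (1 without WT replicate 1, 5 without Abhd15 KO replicate 1, 0 without Abhd15 KO replicate 2, 1 without Abhd15 KO replicate 3). The cause was not tested, except that the muscle covariate removes the muscle list by construction. The macrophage median was −0.20 with and without it (adjusted p = 0.0876 with it). The muscle list reversed without WT replicate 1 (median 0.16) and its median ranged from −1.32 to 0.16 when 1 array was left out. It was called in 17 of 23 alternatives, and the macrophage list in 13 of 23. Of 639 list values over the alternatives that change 1 choice, 611 stayed on their side of the threshold, 16 lost a call and 12 gained one. The Abhd15 difference ranged from 0.03 to 0.22. The neighbours of Abhd15 numbered 5 at an unadjusted p under 0.05 and 0 within 2 or 10 Mb by adjusted p. Of 1168 values of the 56 named genes whose groups overlap, 15 changed sign; the other named genes cannot change sign when arrays are left out.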

Other observations

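The tests in this part were chosen after the values they concern were seen, except the estimated correlation of the muscle list, which was planned.

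Several other genes, picked after their values were seen, were lowest in the same arrays as Angptl8. The amino acid transporter gene Slc7a8 read 7.20 in WT replicate 2 and 8.50 in Abhd15 KO replicate 1 and between 9.91 and 10.98 in the other 6 arrays. Hk2, the hexokinase that insulin induces, read 8.97 and 9.0 against 9.97 to 10.42, and Ppp1r3c, which targets a phosphatase to glycogen, 8.27 and 9.10 against 9.38 to 10.16. Zbtb16, a transcription factor that glucocorticoids induce, was highest in these arrays (9.26 and 9.35 against 7.22 to 8.50), as was the matrix gene Thbs1 (7.22 and 7.64 against 4.85 to 5.67). Not every feeding-induced gene went this way: Fasn read 12.67 and 12.69 in these arrays and 12.43 to 12.67 in the other 6. The mean of the glycolysis list was −0.04 and −0.03 there but lower in WT replicates 1 and 3 (−0.05 and −0.08). Among the arrays labelled Abhd15 KO, however, replicate 1 was the lowest in this list. Hmox1, the heme-degrading enzyme, followed another order, from 6.50 in WT replicate 2 to 9.82 in Abhd15 KO replicate 5. Trim63, a muscle ubiquitin ligase, had the largest residual SD of all genes (1.84) and ranged from 3.46 to 8.31.

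A candidate explanation for the low Angptl8 of 1 array in each genotype is a smaller effect of refeeding in those mice. The fasting list, fixed before the data were examined, had its highest means in the same arrays (0.27 in WT replicate 2 and 0.25 in Abhd15 KO replicate 1), and 0 of the other 6 arrays reached them, the nearest being 0.20. Its members did not all follow. Cited2 and Zbtb16 were highest in both arrays, but Ucp3 was lowest of the 8 arrays in WT replicate 2 (8.255). Irs2 read 6.70 in Abhd15 KO replicate 1, below WT replicate 1 (7.31) and Abhd15 KO replicate 3 (7.01). Trim63, a muscle gene on this list, was highest in WT replicate 1 (8.31). Handling or stress before freezing could not be set aside either. Of the other 6 arrays, 0 reached the immediate early list means of WT replicate 2 and Abhd15 KO replicate 1 (0.49 and 0.24, nearest other 0.10). Not every member of that list followed: Nr4a2 was lowest in both arrays (5.69 and 5.74 against 6.33 to 7.11). Fewer adipocytes as the reason are argued against. Against the other arrays of its genotype Angptl8 was lower by 2.68 log2 in WT replicate 2 and 2.71 in Abhd15 KO replicate 1, while the 18 adipocyte identity genes had a median change of 0.054 (SD 0.26) and 0.14 (SD 0.36). In 8 of 28 lists these arrays held both highest means (fasting response, immediate early, macrophage, interferon, matrix, white adipocyte, fatty acid uptake and oxidation, and other Abhd genes), where a pair drawn at random gives 1 list, so the fasting list is not alone. In 2 lists, clock and ribosomal protein genes, they held both lowest means, where a pair drawn at random also gives 1. This pair was picked by its values in the same data, so neither count is a test against chance. The clock list mean was −0.14 in WT replicate 2 and −0.24 in Abhd15 KO replicate 1, with the nearest other array at −0.04. Food intake was not given in the sources used here.

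The muscle transcripts may come from varying amounts of adjoining skeletal muscle in the tissue taken. The list members moved together inside the groups, with an estimated correlation of 0.905, and the list mean spanned 2.79 log2 in WT and 2.54 in the arrays labelled Abhd15 KO against a group difference of −0.54. None of the 30 members is on another list (0), 13 exceeded 8 log2 in some array, and all 30 passed the filter on dim genes. These counts do not tell which cells made the transcripts, and a level made by brown fat itself is not excluded. A preset correlation too low for such a list is in line with 35 of the 56 splits calling it. An effect of genotype cannot be told apart from chance at 8 arrays (exact permutation p = 0.518).

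Glucose handling is a hypothesis that a larger series could test. Without the pair of arrays lowest in Angptl8, 23 of 26 glycolysis and glucose storage genes were higher in the remaining arrays labelled Abhd15 KO, with a median of 0.10 (camera adjusted p = 0.0122, and adjusted p = 0.901 with an estimated correlation). Without the pair lowest in muscle genes the median was 0.05 (adjusted p = 0.588). Slc2a4 differed by 0.38 with a standard error of 0.12 without the pair lowest in Angptl8 (limma adjusted p = 0.9997). Slc2a4 lies within 10 Mb of Abhd15, so a strain segment carried with the targeted locus was not excluded for it.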
